A study of Mus musculus with 6 samples.

How the data were processed

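G1E-ER-GATA-1 cells are a mouse erythroid precursor line that lacks its own GATA-1 and carries GATA-1 fused to the hormone-binding part of the estrogen receptor, so that estradiol switches GATA-1 on and starts red cell maturation. Per the labels' protocols, the cells received siRNA against Foxo3 or nontargeting siRNA by electroporation at 0 h and again at 24 h, estradiol was added at 24 h, and total RNA was taken at 48 h. Each of 6 RNA samples, 3 per siRNA, was labelled with Cy3 from 0.1 µg of RNA and hybridised alone to a 1-colour Agilent mouse array. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples.

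Per the file headers, the spot intensity in the scanner files was computed by Agilent Feature Extraction 10.7.3.1, which subtracts background, detrends each array and puts a surrogate value in place of a signal that does not exceed background. No normalization between arrays is recorded for these intensity values. The deposited series file holds the same signal for all 6 arrays (largest difference 0) next to the authors' log2 fold change, p-value and adjusted p-value per spot. Per the submitters' processing notes the deposited log2 fold change and p-value came from limma; the normalization behind them is not named. Base 2 for that fold change was read from a comparison with the signals, because that file does not give the base.

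Each array held 62976 spots, of which 3671 were control spots and were left out. Spots marked as outliers by Feature Extraction were set to missing. The signal was taken to log2, the 75th percentile of each array was subtracted, and spots of 1 probe were averaged, which left 55681 probes of 60 bases. Probe names were matched to the mouse RefSeq gene table: 27235 probes through a transcript accession, 3581 through the symbol, 565 through a synonym carried by 1 gene, and 24300 without a match. Probes were kept when well above background on all 3 arrays of at least 1 group (26990 probes), and the brightest kept probe stood for its gene, which gave 19212 genes and unnamed features, 12679 of them with a RefSeq symbol. Positions are those of the array design on mouse build mm9.

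Groups were compared with limma's moderated test (lmFit and eBayes, two-sided) without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all 19212 tested features. Adjusted p-values given for genes come from this limma model unless credited to the authors. Values given for single probes, such as those of Foxo3 and Foxo4, come from the same test run on the 26990 kept probes and adjusted over them. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over 26 lists, and again with an estimated correlation and with fry. For a gene well above background on no array of 1 group, a bound replaces the fold. The mean of the other group is set against the mean of the dim group after the dim values are raised. Each is raised at least to the lowest well-above-background level of that array. Brighter spots can still miss the mark: on Foxo3 siRNA replicate 3 that level was −2.50, and the RefSeq Foxo3 probe missed it at −1.89. The bounds are therefore approximate.

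The groups, the test, the gene lists, the rule for named genes and the processing alternatives were fixed before the data were examined. The rule named Foxo3, then the 12 largest rises and 12 largest falls in log2 fold change among genes past an adjusted p of 0.05 whose values in 1 group all lay beyond those of the other. Some genes that met these rules, and a result resting on them, are not reported here. Placeholder symbols were passed over (1 among the rises and 11 among the falls). It also named up to 4 members of each fixed list with the smallest adjusted p, and Foxo1, Foxo4 and Foxo6. Other members of the fixed lists named in the text were chosen after their values were seen. Of the 118 genes named by the rule, 30 had more than 1 kept probe, and in 0 of them were probes called in both directions. The choice between the 2 Foxo3 probes was not fixed in advance beyond showing both. The one designed on the RefSeq mRNA was put first after both had been seen, although the brightest-probe rule takes the other.

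Signal over background stands in for depth on these arrays. Foxo3 siRNA replicates 1 to 3 had 30619, 37532 and 20343 spots well above background, and nontargeting replicates 1 to 3 had 33513, 31611 and 32182. Surrogate values filled 50.2% of the non-control spots of Foxo3 siRNA replicate 3, against 16.7% to 29.3% on the other arrays. Its lowest signal was 24.1, against 3.48 to 4.29 elsewhere. No spot was saturated. Correlations of log2 signals lay between 0.986 and 0.994 within groups and between 0.968 and 0.981 across groups. There were 3 arrays per group, and their number limits the precision.

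The alternatives were quantile normalization, scaling to the median, normexp background correction with an offset of 50, the deposited series table, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, keeping marked spots, eBayes with trend and robust options, array weights, the replicate number as a block, other thresholds, and leaving out each array in turn. A block for slide or scan batch had been planned and was not run, because all 6 arrays shared 1 slide and 1 scan. The file headers place the 3 nontargeting arrays and Foxo3 siRNA replicate 1 in 1 row of that slide, and the other 2 Foxo3 siRNA arrays in the next. Slide row was therefore added, after the data were seen, as a block and by keeping the arrays of 1 row.

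The model was tested on simulated data with the real spread of each gene and known changes in few genes. It called 1 of 67 genes changed by 0.5 on the log2 scale, 27 of 67 changed by 1 and 57 of 66 changed by 2, with 4 calls among 18911 unchanged genes. Noise was drawn independently for each gene, and slide row and surrogate values were not imitated. These rates therefore need not hold for the real arrays, where far more features were called. Analyses ran in R 4.3.3 with limma 3.58.1, Biostrings 2.70.1 and data.table (version 1.17.8), and plots were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.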

Results

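Foxo3 mRNA was lower in the cells that received Foxo3 siRNA, as read by the probe designed on the RefSeq transcript. Foxo3 encodes a forkhead transcription factor that, as background, induces cell cycle inhibitors, autophagy genes and antioxidant enzymes. This probe (mouse build mm9, chromosome 10, 41905610 to 41905669, minus strand, sequence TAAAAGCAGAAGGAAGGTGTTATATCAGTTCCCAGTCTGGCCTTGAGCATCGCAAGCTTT) fell by 2.42 on the log2 scale (SE 0.337, n = 3 arrays per group, limma adjusted p = 0.00511), which left 18.7% of the nontargeting level. Its scaled log2 signal was −0.47, −1.29 and −1.89 with Foxo3 siRNA and 1.20, 1.28 and 1.12 with nontargeting siRNA, and it was well above background on 2 of the 3 Foxo3 siRNA arrays. The other Foxo3 probe, designed on a cDNA clone 61618 bases away (41967288 to 41967347), gave 0.26 (SE 0.161, adjusted p = 0.242). This probe is the brighter of the pair and 29 of its 60 bases are T. The knockdown therefore rests on 1 probe, which was put first after both had been seen. In the authors' own table the same probes read −2.28 (adjusted p = 0.0398) and 0.22 (adjusted p = 0.562).

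**Figure D1:**
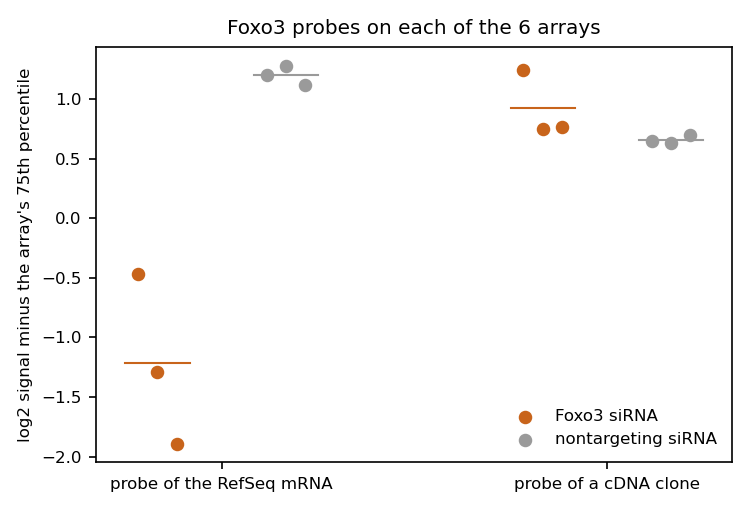
Scaled log2 signal (log2 signal minus the 75th percentile of the array) of the 2 Foxo3 probes on each of the 6 arrays, with group means as lines. The RefSeq probe lies between −1.89 and −0.47 with Foxo3 siRNA and between 1.12 and 1.28 with nontargeting siRNA, while the clone probe has a group difference of 0.26.

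Among the other FoxO genes, the brightest Foxo4 probe gave −0.75 (adjusted p = 0.145), and its 2 probes on the RefSeq mRNA were lower, at −0.97 (adjusted p = 0.00492) and −0.88 (adjusted p = 0.033). These RefSeq probes overlap (chromosome X, 98454966 to 98455025 and 98454974 to 98455033), so they are not separate readings. All 3 Foxo4 probes were well above background on 2 of the 3 Foxo3 siRNA arrays. No probe of Foxo1 or Foxo6 passed the filter on dim signals.

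The 12 largest rises included Bub1 and Kif2c, both of the fixed mitosis list. Bub1, a kinase of the spindle checkpoint, rose by 3.86 on the log2 scale (SE 0.117, adjusted p = 0.000212), or 14.5-fold. Aspm, which acts at spindle poles, rose by 3.55 (SE 0.156, adjusted p = 0.000351), Prr11 by 3.51 (2 of 3 nontargeting arrays well above background) and Arhgef39 by 3.56 (SE 0.113, adjusted p = 0.000212). Pbk, a mitotic kinase, rose by 3.56, with 1 of the 3 nontargeting arrays well above background, and Kif2c, a microtubule depolymerising kinesin, rose (adjusted p = 0.00197) with 0 of 3 on this probe and 1 of 3 on another, so the size of its rise is uncertain. Neil3, a DNA glycosylase, and Mpp2 were higher, with approximate bounds of 7.19-fold and 5.86-fold. Bounds are given since neither was well above background on any nontargeting array. Without Foxo3 siRNA replicate 3 the bound for Mpp2 was 3.81-fold. Ldc1 (3.76, with 1 of 3 nontargeting arrays above background; 4.71 without nontargeting replicate 2, and its call was lost in 7 of 18 alternatives), Gipr (3.32), Hacd1 (3.28) and Pcx, the pyruvate carboxylase of mitochondria (3.20), completed the 12 largest rises. With normexp background correction and an offset the rises were smaller on the log2 scale, at 2.36 for Bub1, 1.87 for Prr11, 1.70 for Pbk, 1.61 for Ldc1, 1.23 for Mpp2 and 1.16 for Neil3, so the bounds for Mpp2 and Neil3 hold only without it.

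At the lower end, Nyx fell by 4.64 on the log2 scale (SE 0.239, adjusted p = 0.000384) and was well above background on 2 of 3 Foxo3 siRNA arrays. Lzts2 fell by 3.43 (SE 0.252, adjusted p = 0.000844) with all 6 arrays above background, and Lgals3, which encodes galectin-3, by 3.23. Klc3, a kinesin light chain, fell by 3.53 (2 of 3 Foxo3 siRNA arrays above background), and its other kept probe gave −2.45. Tpm4, a tropomyosin, was lower with an approximate bound of 8.50-fold. Those of Cd59b, a complement inhibitor, and Clec4a3, both also lower, were 6.23-fold and 4.76-fold. Without Foxo3 siRNA replicate 2 these bounds were 5.32, 3.87 and 2.96, and without its replicate 3 they were 14.4, 10.6 and 8.08. The bound for Cd59b was also 3.96 without nontargeting replicate 2 and 11.6 without replicate 1, and its call (adjusted p = 0.0404) was lost in 9 of 18 alternatives. With normexp and an offset Nyx was at −3.31, Cd59b at −1.69, Tpm4 at −1.48 and Clec4a3 at −1.45, so the bounds hold only without it. Pramel51 (−3.51), Tmprss9 (−3.18), Kctd19 (−3.10) and Ahsg (−3.06) were each above background on 2 of the 3 Foxo3 siRNA arrays, and the call of Tmprss9 was lost in 6 of 18 alternatives. Pramel51 is reported as uncertain, because binding of other transcripts to its probes was not excluded. Falls above background on fewer than 3 Foxo3 siRNA arrays passed the filter only through the nontargeting arrays, where they were high.

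**Figure D2:**
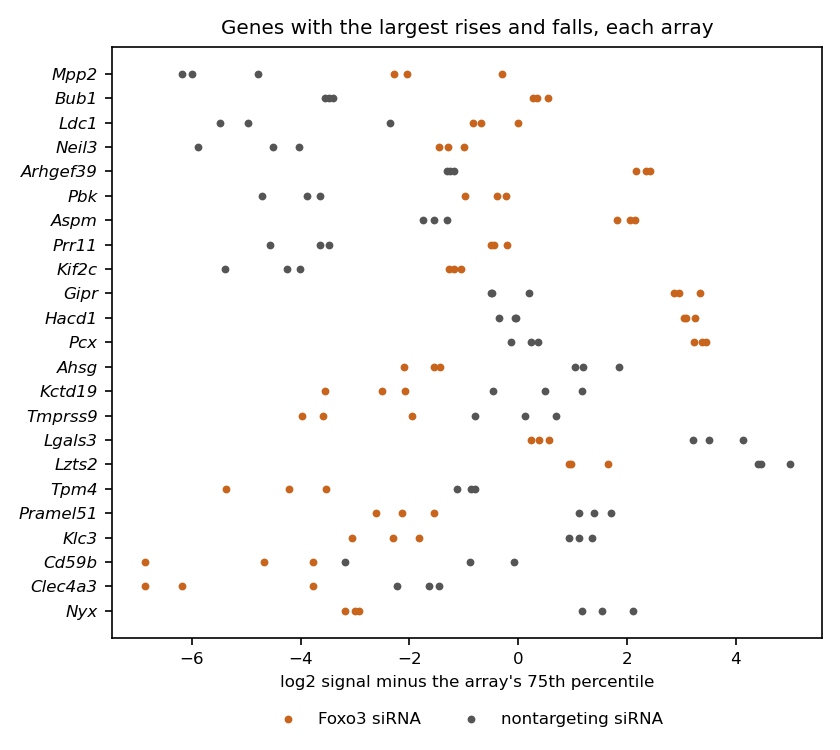
Scaled log2 signal of the 12 genes with the largest rises and of 11 with the largest falls, with 1 point per array in each group. The 3 values of each group lie apart in every gene plotted, by the rule that chose them; Bub1 differs by 3.86 and Lzts2 by −3.43.

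In all, limma called 5299 of 19212 features at an adjusted p under 0.05 (27.6%), 2644 higher and 2655 lower with Foxo3 siRNA; 8518 had an unadjusted p under 0.05. A change of at least 2-fold was found for 1445 of the called features, 787 higher and 658 lower. The 3 values of each group lay wholly apart in 9792 tested features (51.0%), against 10% for 3 and 3 interchangeable arrays without a filter. These arrays are not interchangeable, since slide row and the raised floor of Foxo3 siRNA replicate 3 differ with group. The excess over 10% is therefore not a measure of the siRNA effect alone. The median log2 fold change of all tested features was −0.146 under the 75th percentile scaling and 0.158 when arrays were scaled to their medians. Under the 75th percentile scaling it was −0.000543 with the filter on all 6 arrays and 0.0268 without a filter. This shift therefore also depends on which dim probes are tested, and the sign of small changes is uncertain. With median scaling 4076 features were called and the share of higher calls was 78.0%, against 49.9%. That share was 55.2% with the filter on all 6 arrays and 67.5% without a filter, so the balance of rises and falls depends on scaling and filter. Spike-in control spots, not used for scaling, differed between groups by −0.404 (E1A_r60_a20) to 0.162 (E1A_r60_3, a dim control and the only higher one). Scaling to them was not run, so a common shift of the fold changes is not excluded. The authors' table marks 1354 spots at an adjusted p under 0.05, 882 higher and 472 lower. Of the spots marked there, 1272 were also called here with the same sign and 0 with the opposite sign. With slide row as a block, a comparison that rests on Foxo3 siRNA replicate 1 alone, 1552 features were called.

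The mitosis list rose as a whole: 41 of its 41 tested members were higher past the threshold (41 adjusted over the list alone), with a median log2 fold change of 2.28 over the 40 without a missing value (camera adjusted p = 4.5e-35; adjusted p = 0.237 with an estimated correlation). Besides Bub1, Birc5, or survivin, rose by 3.19, Aurka by 2.64 and Plk1 by 2.50, the last pair being kinases of spindle assembly. The smallest rise was that of Bub3 (0.46). In the DNA replication list 25 of 43 members rose and 1 fell, or 33 and 1 adjusted over the list alone (median 0.68, camera adjusted p = 1.2e-13; adjusted p = 0.764 with an estimated correlation). Mcm5 and Mcm3, subunits of the replicative helicase, rose by 2.22 and 1.69, and the transcription factor E2f2 rose by 2.39. In the ribosome biogenesis list 11 of 46 members were higher and 0 lower, both over all genes and adjusted over the list alone (median 0.40, camera adjusted p = 1.6e-07; adjusted p = 0.764 with an estimated correlation, and not called by fry, adjusted p = 0.0619). Polr1a, the large subunit of RNA polymerase I, rose by 1.03 on 1 of 2 kept probes (the other gave 0.65, adjusted p = 0.134), Nop16 by 0.79, Wdr12 by 0.71 and Polr1c by 0.62.

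Genes of glycolysis and the hypoxia response rose in 18 of 25 cases and fell in 1, or 19 and 1 adjusted over the list alone (median 1.25, camera adjusted p = 2.6e-09; adjusted p = 0.764 with an estimated correlation). Ankrd37 rose by 2.31, Slc2a1, the glucose transporter, by 1.72, Higd1a by 1.29 and Pfkm, a phosphofructokinase, by 1.28. The exception was Bpgm, which makes 2,3-bisphosphoglycerate in red cells and fell by 0.53. Gapdh (0.07, adjusted p = 0.695) and Aldoa (0.05, adjusted p = 0.80) did not pass. Sterol synthesis genes rose in 14 of 24 cases with 1 fall, or 16 and 1 adjusted over the list alone (median 0.58, camera adjusted p = 6.8e-06; adjusted p = 0.764 with an estimated correlation). Dhcr7 rose by 1.56, Tm7sf2 by 1.34, Pmvk by 0.99 and Ebp by 0.68.

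The FOXO target list moved down: 20 of 34 members fell and 1 rose, or 21 and 2 adjusted over the list alone (median −0.73, camera adjusted p = 7.0e-05; adjusted p = 0.764 with an estimated correlation). Pink1, a kinase of mitophagy, fell by 1.77, Txnip, an inhibitor of thioredoxin, by 1.74, and the stress protein gene Sesn1 by 1.05. Ulk1, which starts autophagosome formation, fell 2.83-fold. The member that rose was Bnip3 (1.56), which the hypoxia list also holds. Catalase (Cat, 0.06, adjusted p = 0.734) and Sod2 (−0.16, adjusted p = 0.262) did not pass. The p53 target list also moved down, with 14 of 21 lower and 1 higher, both over all genes and adjusted over the list alone (median −0.76, camera adjusted p = 1.1e-05; adjusted p = 0.764 with an estimated correlation). Trp53inp1 fell by 1.43, Zmat3 by 1.26 and Sesn2 by 1.19, while Rrm2b, a ribonucleotide reductase subunit, rose by 1.19 (2 of 3 Foxo3 siRNA arrays above background). These lists share 5 tested genes, all of which fell; among the 16 p53 targets outside the FOXO list 9 fell and 1 rose (median −0.50).

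Autophagy genes went both ways and the list was not called in the main comparison: 14 of 36 fell and 4 rose, or 15 and 5 adjusted over the list alone (median −0.11, camera adjusted p = 0.185; fry adjusted p = 0.0338). It was called down without the filter on dim probes (adjusted p = 0.0267), with the filter on all 6 arrays (adjusted p = 0.0244) and without nontargeting replicate 1 (adjusted p = 0.0432). Ulk1 fell 2.83-fold, and on the log2 scale the cargo receptor Sqstm1 fell by 1.47, Trp53inp1 by 1.43 and Rb1cc1 by 1.36 (its other kept probe gave −0.76). The median of the list was 0.20 when arrays were scaled to their medians, so the sign of the list median depends on the scaling. In the lysosome list 5 of 32 fell and 1 rose (camera adjusted p = 0.449). Cd63 fell by 1.84, with 2 of 3 Foxo3 siRNA arrays above background, Tfeb, a regulator of lysosome genes, by 1.01, Ctsd by 0.92 and Scarb2 by 0.86.

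The RNA exosome list, whose products degrade and trim RNA from the 3′ end, had 6 members higher and 2 lower among 19, or 8 and 2 adjusted over the list alone (median 0.30, camera adjusted p = 0.00996; adjusted p = 0.764 with an estimated correlation). Exosc8 rose by 1.35, Mphosph6 by 1.11, Exosc5 by 0.80 and Exosc10 by 0.56, while Exosc2 fell by 0.51. The call of the list was lost on the arrays of slide row 1 (adjusted p = 0.055).

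**Figure D3:**
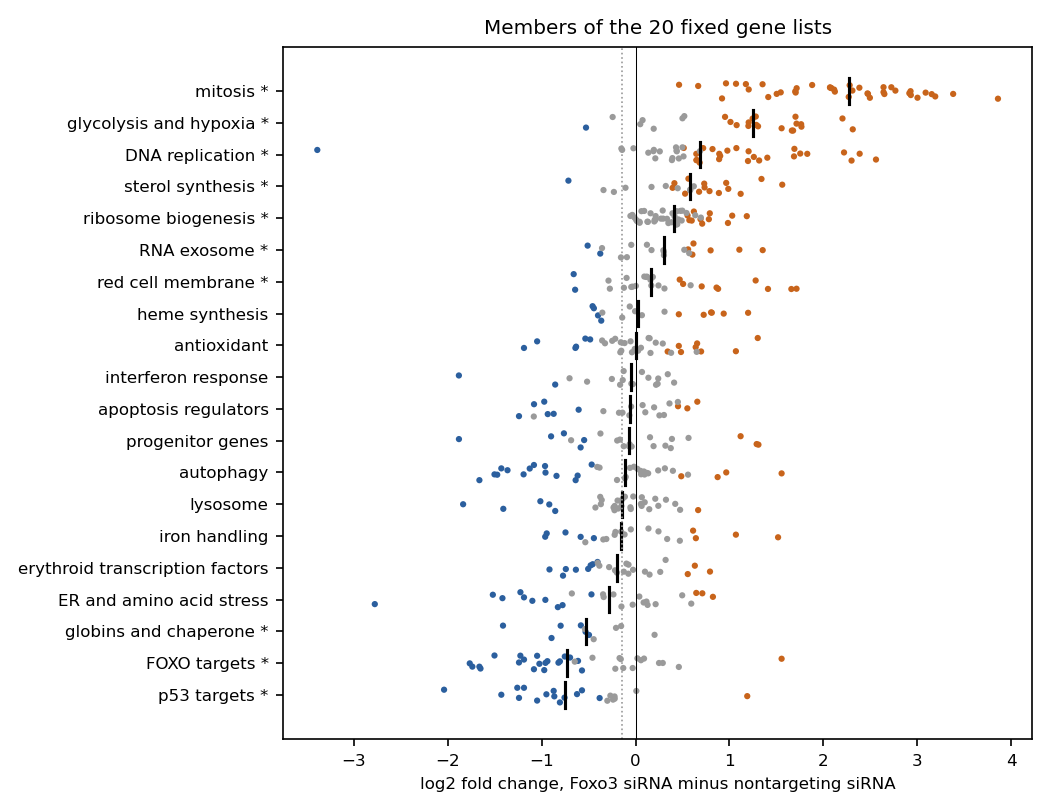
Log2 fold change (Foxo3 siRNA minus nontargeting siRNA) of every tested member of the 20 fixed pathway lists, with 1 point per gene, coloured where the adjusted p is under 0.05 (orange higher, blue lower). Black bars are list medians, from 2.28 for mitosis to −0.76 for p53 targets, the dotted line is the median of all features (−0.146), and asterisks mark the lists called by camera at the preset correlation.

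Erythroid genes did not move as 1 group. In the globin list 6 of 11 members fell and 0 rose, or 8 and 0 adjusted over the list alone (median −0.53, camera adjusted p = 0.0107; adjusted p = 0.764 with an estimated correlation). Hbb-y fell by 1.41, Hbq1b by 0.89, Hbq1a by 0.80 and Hbb-b2 by 0.58, the last with its call lost in 10 of 19 alternatives. Globin values are uncertain, because the paralogs are nearly alike in sequence and their probes can bind one another's transcripts. Several are also among the brightest probes, which quantile normalization evens out between arrays by construction. A call lost under it therefore says little. The call of the list was lost under quantile normalization (median −0.16), under median scaling (median −0.23), with slide row as a block (median −0.30, adjusted p = 0.061), on the arrays of slide row 1 (adjusted p = 0.055) and by fry (adjusted p = 0.0611). The red cell membrane list rose, with 9 of 27 higher and 2 lower, both over all genes and adjusted over the list alone (median 0.17, camera adjusted p = 0.0107; adjusted p = 0.764 with an estimated correlation). Slc2a1 rose by 1.72, Rhag, of the Rhesus complex, by 1.41, Icam4 by 1.28 and Cd24a by 0.70. The call of this list was lost with the filter on all 6 arrays (adjusted p = 0.0797). Among 16 heme synthesis genes 6 rose and 4 fell, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.247). Ppox rose by 1.20, Alad by 0.94, Abcb6 by 0.81 and Uros by 0.73 (its other probe gave 0.50, adjusted p = 0.0618), while Alas2, the first enzyme of the pathway in red cells, fell by 0.40 (adjusted p = 0.0492), a call lost in 12 of 19 alternatives.

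Of 25 erythroid transcription factor genes 8 fell and 3 rose (median −0.20, or 0.11 with median scaling; camera adjusted p = 0.286). Lmo2 fell by 0.92, Mafk by 0.77 and Gfi1b by 0.74, and Hmgb2 rose by 0.79. Gata1 itself gave −0.08 (adjusted p = 0.671) and Klf1 0.15 (adjusted p = 0.43). Among iron genes, 4 of 21 rose and 5 fell (camera adjusted p = 0.916). Tfr2, a transferrin receptor, rose by 1.52 and Hmox1, heme oxygenase, by 1.07, while Iscu fell by 0.96 and Steap3 by 0.95. In the progenitor list 3 of 22 rose and 5 fell (camera adjusted p = 0.819, direction up, although its median of −0.07, or 0.24 with median scaling, and its mean of −0.03 are negative). Vim rose by 1.31, Lyl1 by 1.29 and Samsn1 by 1.12, whereas Egr1 fell by 1.88.

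The remaining pathway lists were not called in the main comparison. In the antioxidant list 8 of 34 rose and 6 fell; Nqo1 rose by 1.30 and Sesn2 fell by 1.19. In the stress list 10 of 26 fell and 3 rose (median −0.29, or 0.02 with median scaling; camera adjusted p = 0.23). It was called down without the filter on dim probes (adjusted p = 0.035) and without nontargeting replicate 1 (adjusted p = 0.0375). There Slc7a11, the cystine transporter, fell by 2.78 with 2 of 3 Foxo3 siRNA arrays above background, Atf5 by 1.52 and Herpud1 by 1.23. Among 22 apoptosis regulators 3 rose and 6 fell; Bbc3, which encodes PUMA, fell by 1.24, Bid by 0.94 and Bax by 0.87, and Bcl2l2 rose by 0.55. In the interferon list 2 of 17 fell, Mx2 by 1.88 (2 of 3 Foxo3 siRNA arrays above background) and Oas3 by 0.86 (call lost in 7 of 19 alternatives), and 0 rose. Its median was −0.04 (0.26 with median scaling) and its mean −0.18, while the direction of the test was up (camera adjusted p = 0.916).

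Marker lists of blood and stromal cells were not called in the main comparison. Of 13 erythroblast markers 2 rose and 1 fell, or 2 and 0 adjusted over the list alone. Rhag rose by 1.41 and Tfrc by 0.61 on 1 of its 3 kept probes (the others gave 0.35 and 0.36 and did not pass), and the fall was that of Alas2. Of 13 megakaryocyte markers 4 rose and 1 fell (camera adjusted p = 0.292, direction up with a mean of 0.29 and a median of −0.15, or 0.15 with median scaling and 0.03 with quantile normalization). It was called up with slide row as a block (median 0.60, adjusted p = 0.019) and on the arrays of slide row 1 (adjusted p = 0.0369). Treml1 rose by 2.51, Itga2b by 1.27 and Gp1ba by 0.59, and Itgb3 fell by 0.79. Among the 6 mast cell markers Hdc fell by 1.22, with 2 of 3 Foxo3 siRNA arrays above background, and 0 rose. None of the 6 granulocyte or monocyte, 5 lymphocyte or 3 fibroblast markers tested passed the threshold, and Csf1r (−0.91, adjusted p = 0.0622), Cd3e (−0.48, adjusted p = 0.0617) and Acta2 (−0.34, adjusted p = 0.0854) came nearest in each. The granulocyte or monocyte list was called down without nontargeting replicate 3 (adjusted p = 0.0478).

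Some large falls came from genes that lie next to each other. On chromosome 12, between 88858331 and 89414373, 15 probes of 9 genes, Pramel51 and predicted or unnamed ones, fell by 3.01 to 5.04 on the log2 scale. Gm8300 (−4.93 and −5.04 on overlapping probes), Gm2016 (−3.82 to −4.61) and Gm2022 (−4.02 and −4.45) belong to this group, whose values are uncertain because several of the probes are similar in sequence. Another kept Gm8300 probe gave −1.78 and did not pass (limma adjusted p = 0.291). The other 13 kept probes inside the interval had a median of −0.16, and 1 of them was lower past the threshold. This region was picked from 5 looked at after their values were seen.

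**Figure D4:**
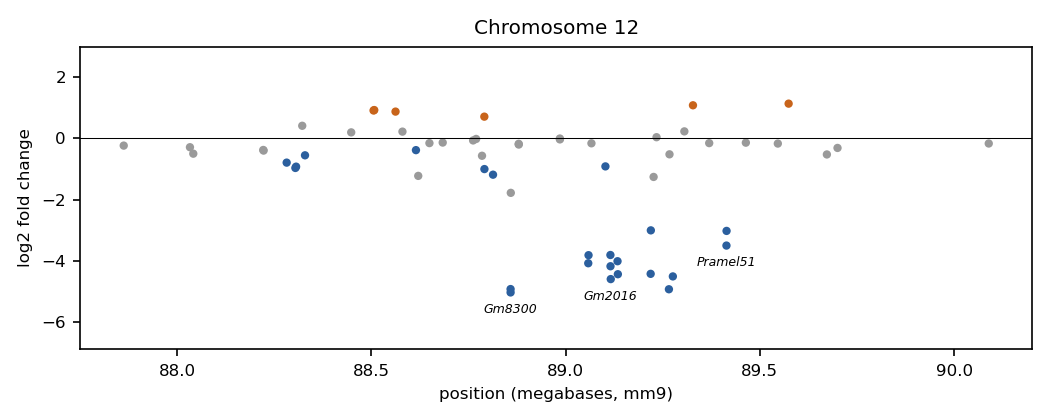
Log2 fold change (Foxo3 siRNA minus nontargeting siRNA) of each kept probe by its position on mm9, within 1 megabase of the chromosome 12 group (orange higher and blue lower past an adjusted p of 0.05, grey not past it). The 15 fallen probes on chromosome 12 lie between −5.04 and −3.01.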

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

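No result met a formal rule for a closer look, since groups of 3 are not tested for outliers and there is 1 contrast. Chosen only after the result was seen were the tests of the GATA-1 response and of copy number on chromosome 12. So were the drawing of that region and the look at genes of the 2-cell embryo. With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. The real split called 5299 features and the highest of the other splits called 0, so 1 of 10 gave as many; unadjusted p-values under 0.05 numbered 8518 in the real split. For the fixed lists, the real split called 10 and the highest other called 12, and 3 of 10 splits called at least 10. The split with 12 set Foxo3 siRNA replicates 2 and 3, the only arrays in their slide row, with nontargeting replicate 1 against the rest, and with slide row as a block 10 lists were called, with the megakaryocyte markers in place of the globins. That block leaves Foxo3 siRNA replicate 1 alone against the nontargeting arrays. The number of lists called at the preset correlation therefore does not set the real grouping apart, and with an estimated correlation 0 lists were called.

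The mitosis list rose on each Foxo3 siRNA array, with all 41 members above every measured nontargeting value. Slide row is argued against by replicate 1, which shares the row of the nontargeting arrays and had a list median 2.10 above their mean. The raised floor of replicate 3 is argued against by the median without it (2.22), and the GC content of the probes by the median over 100 probes of like GC content and brightness (also 2.22). A weaker response to GATA-1 as a whole could give more dividing cells and stays open: of 21 called heme synthesis and red cell membrane genes 6 fell and 15 rose, within what an even chance allows. Of 11 globin genes 6 fell and 0 rose, but the call of that list was lost with an estimated correlation and under several processing alternatives. That cells with less Foxo3 kept dividing is only a hypothesis, which counts of mitotic cells after several different Foxo3 siRNAs would test; neither division nor effects of the siRNA on other transcripts were measured here.

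The group of neighbouring genes on chromosome 12 fell by more than any other window of 9 genes (window median −4.20, against −1.36 for the lowest of 200 shuffled gene orders). The raised floor of Foxo3 siRNA replicate 3 is argued against by a median of −4.0 over the fallen probes without it, and a copy number change reaching 1 megabase to each side by a median of −0.20 over 28 other genes there. Whether similar copies are read as 1 transcript cannot be told apart from separate falls: 7 of 15 probes share at least 45 of 60 bases with a fallen probe of another gene, and 5 share under 30. The latter bound, set beforehand as speaking against it, was wrong, since probes at different points of copied transcripts share no bases; in the interval as first drawn 2 of 8 probes shared 45. The other 13 kept probes inside the interval had a median of −0.16, and 1 of them was lower past the threshold. If those probes read transcripts from there, that argues against a deletion of the whole interval. Genes of the 2-cell embryo were also looked at, after the values were seen. Of 21 probes of such genes, 3 were well above background on all 3 nontargeting arrays. Tcstv1 fell by 0.98 (limma adjusted p = 0.0122), while Dux (−0.24) and Zfp352 (−0.50) did not pass. So few readable probes decide nothing. No other biological explanation was tested, and smaller deletions or silencing of the group alone in some cultures might also give the fall.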

How the results depend on the processing

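Slide row and the choice of the Foxo3 probe were added as alternatives after the data were seen. The count of 5299 changed features was 1175 without a filter on dim probes, where 34740 features were tested, 8569 with array weights and 8003 at an adjusted p under 0.1. It was 1552 with slide row as a block and 600 on the arrays of slide row 1; both rest on Foxo3 siRNA replicate 1 alone, assumed to vary like the others. Leaving out 1 array gave 2172 to 4568: 2885 without Foxo3 siRNA replicate 2, 2879 without its replicate 3, 3026 without nontargeting replicate 1 and 2172 without its replicate 2. Why these counts differ was not tested, and leaving out an array also lowers the number of arrays.

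The Foxo3 RefSeq probe gave −2.42 without the filter too, with an adjusted p of 0.0614 over more tests, was −1.67 with slide row as a block, the value of replicate 1 alone, and was −2.79 to −2.08 when 1 array was left out. On the brightest probe of the gene Foxo3 was 0.26 (adjusted p = 0.232 in the gene model), because another probe is read; the filter on all 6 arrays dropped the RefSeq probe and gave no value. Lists called numbered 10, 0 with an estimated correlation and 10 to 12 when 1 array was left out. The planned slide or scan block was not run (1 slide, 1 scan).

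The labels do not say what a replicate number shares. Deviations of same-numbered samples correlated at 0.18, −0.33 and 0.13, and 2 of 6 samples correlated best with their own. A step shared by number is not excluded, since some spike-in controls were highest in replicate 1 of both groups. E1A_r60_a97 read 4.34, 3.64 and 3.73 with Foxo3 siRNA and 4.81, 4.09 and 3.84 with nontargeting siRNA. With the replicate number as a block 5486 features and 10 lists were called, and Foxo3 was −2.42. Over the alternatives, 1973 of 2194 values of 117 named genes stayed on the same side of the threshold, 187 lost the call and 34 gained it, and 3 changed sign. Of 543 list values these were 516, 18 and 9, and the direction of the list test changed in 23. That count is not one of list medians, several of which changed sign with median scaling. None was called in the opposite direction. Normexp adds an offset of 50 to every signal, which by its construction shrinks fold changes of dim genes (Neil3 1.16). Foxo3 siRNA replicate 3, with the fewest spots above background, limits the dim genes.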

Other observations

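The 30 gene families below were chosen by name after the data were seen, as were the tests of neighbouring genes except that of GC content. With camera at the preset correlation 13 of the 30 were called, 12 up and 1 down, and 0 with an estimated correlation (smallest adjusted p = 0.246). Mitochondrial ribosome genes had the smallest adjusted p, with 37 of 78 higher and 0 lower (median 0.35, adjusted p = 1.9e-13; adjusted p = 0.246 with an estimated correlation). Complex I genes of the respiratory chain had 21 of 48 higher and 1 lower (median 0.31; adjusted p = 0.246 with an estimated correlation). Ndufa4l2, a member by name that hypoxia induces, rose by 2.30. Genes of the cytosolic ribosome showed no such shift, with 3 of 79 higher and 1 lower (median −0.09, or 0.21 with median scaling; adjusted p = 0.932).

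Fanconi anaemia genes rose in 5 of 8 cases with 0 falls (median 0.73), led by Fanci (2.04), and centromere protein genes in 12 of 19 with 1 fall (median 0.69), led by Cenpe (3.00); both have an adjusted p of 0.246 with an estimated correlation. Among 26 kinesins 9 rose and 3 fell (median 0.13, adjusted p = 0.246 with an estimated correlation), and the risers Kif4 (2.73), Kif23 (2.28) and Kif20a (2.07) act in cell division. These risers and Cenpe are members of the fixed mitosis list, so the kinesin and centromere families partly repeat that result. Histone genes went both ways, with 14 of 62 higher and 17 lower; H2ac4 rose by 2.32 and H4c9 fell by 1.55. Histone values are uncertain, because the copies are similar. Olfactory receptor genes, mostly dim, had 34 of 171 lower and 0 higher (median −0.50; adjusted p = 0.576 with an estimated correlation). Their median probe lay at −0.52, and at −0.20 over probes of like GC content and brightness. Dim probes pass the filter more easily through the nontargeting arrays, which can favour falls. Foxo3 siRNA replicate 3 had 34.3% of its spots well above background, against 51.6% to 63.3% on the other arrays.

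A further hypothesis was that neighbouring genes change together. Over 15019 pairs of neighbours whose names start differently, log2 fold changes had a rank correlation of 0.116. The highest of 1000 shuffled gene orders gave 0.0261. Unnamed clones and copied genes can carry different names and still read 1 transcript or similar ones. The comparison therefore cannot say whether shared families or copies account for the correlation. It was 0.100 after the trend with GC content and brightness of the probes was taken out (highest shuffled value 0.022). It is taken across genes, which are not independent replicates, and genes 20 places apart gave 0.00913. Overlapping transcripts and shared promoters were not tested.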
